A study of Drosophila melanogaster with 15 samples.

How the data were processed

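RNA was measured on Affymetrix Drosophila arrays from neurons of third-instar larval brains. Per the labels' protocols, larvae were raised at 25 °C in 12 h of light and 12 h of dark, brains were dissociated for 2 h in collagenase and dispase, the brightest cells were sorted by flow cytometry into extraction buffer, and mRNA was amplified with the NuGen WT-Ovation kit to give biotin-labelled cDNA. Dissociation and amplification of RNA from few cells act on every array, and a transcript near the lower end of the scale can be lost in some arrays and kept in others. Groups were taken from the sample titles and the genotype labels, 3 arrays each, which the titles call biological replicates. The labels' protocol names RFP-positive cells for every array, while the genotype labels give GFP to wild-type LNvs and elav neurons, and the tissue label of the elav arrays also reads as LNvs. The elav arrays were taken as elav neurons from their titles and genotype.

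The values analysed are the deposited log2 values, which were made with GCRMA, per the submitters' processing notes. The GCRMA version, the grouping of arrays in that step and any later filter are not given in the sources used here. GCRMA subtracts a background modelled from probe sequence, summarises probes to probe sets and normalizes across arrays, so that transcripts below background gather near the lowest values, and differences against such a group can be understated. The table held 18869 probe sets, of which 100 were controls and were left out. Of the others 13646 had 1 gene symbol in the platform annotation, 402 had several and 4721 were unnamed here, and only the first kind was named. No symbol changed when matched to a current gene table, and 103 probe sets kept the platform symbol because their identifier was not in that table. The 11981 genes were represented by the probe set with the highest mean over all arrays, and other probe sets of a named gene were compared with it where they differed.

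Probe sets with a log2 value of at least 4 in at least 3 of the 15 arrays were tested (5829 probe sets for 4721 genes). Linear models with a mean per group were fitted to all 15 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the 5 groups shared an estimate of the spread for each probe set (prior degrees of freedom 7.46). The 5 comparisons were wild-type LNvs against elav neurons at ZT15, wild-type LNvs at ZT15 against ZT3, per0 against wild type, cyc0 against wild type, and cyc0 against per0. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The number of arrays limits the precision. In simulated data with known differences, a log2 difference of 2 was recovered for 22% of changed probe sets between LNvs and elav neurons and 14% between the times, and a log2 difference of 4 for 96% in both. For per0, cyc0 and cyc0 against per0 the shares were 20%, 30% and 34% at a log2 difference of 2 and 92%, 92% and 98% at 4.

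The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, up to 12 genes with the largest positive and 12 with the largest negative difference among those that passed without overlap between the arrays, a fixed set of clock and marker genes (per, tim, vri, Pdp1, cwo, Clk, cyc, cry, Pdf, Irk1, Shaw, elav and w), and up to 4 members of each list with the smallest p. The 23 lists were CLK/CYC targets of the clock loop, other clock factors and kinases, LNv-associated genes, peptide processing and dense-core vesicles, neuropeptides other than Pdf, pan-neuronal and synaptic vesicle genes, fast transmitter and monoamine markers, potassium channels, sodium, calcium and cation channels, neurotransmitter receptors, ribosomal proteins, oxidative phosphorylation subunits, heat-shock and chaperone genes, activity-regulated and JNK-response genes, and antimicrobial and immune genes. As markers of other cells there were lists for neuroblasts, the cell cycle, immature neurons, glia, hemocytes, fat body, photoreceptors and muscle. Some genes stand in more than 1 list, such as sNPF, cac, para, cry and Clk. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and by camera with the correlation estimated from the data. Of the lists that passed, the clock targets in 4 comparisons and the activity-regulated genes in LNvs against elav neurons also passed with the estimated correlation. For the lists that passed, median, mean and test had the same sign, and the median kept its sign after centring and after quantile normalization.

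The alternatives were no filter, a stricter filter, centring of each array on its median, quantile normalization, a prior with trend and robust estimation, array weights, a fit to the 6 arrays compared, 1 probe set per gene, a minimum fold, the replicate number as a block, all 12 LNv arrays against elav neurons, and leaving out each array in turn. Overlaps between comparisons with the same wild-type arrays were set beside 50 simulations of unchanged groups. For the probe sets called in both mutants, further simulations drew noise for each probe set independently or reassigned the residuals of whole arrays with random signs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3. Raw scanner intensities were not used here. Clk and Shaw were on the array but stayed below the filter, and w had no named probe set here.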

Results

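Expression was profiled on 15 Affymetrix Drosophila arrays of neurons sorted by fluorescence from the brains of third-instar larvae. The cells of interest were the ventral lateral neurons (LNvs), the pacemaker neurons that make the neuropeptide Pigment-dispersing factor (Pdf), of which there are 8 per brain according to the series description. The arrays formed 5 groups of 3, namely wild-type LNvs at zeitgeber time (ZT) 3, wild-type LNvs at ZT15, per0 LNvs at ZT15, cyc0 LNvs at ZT15, and neurons labelled through the pan-neuronal elav driver at ZT15. In the cycle of 12 h light and 12 h dark, ZT3 lies 3 h after lights-on and ZT15 lies 3 h after lights-off. The wild-type LNvs carried Pdf-Gal4 with UAS-GFP and both mutants carried Pdf-RFP, so that reporter and genotype cannot be told apart where a mutant is compared with wild type. Between 3520 and 5436 of the 18769 probe sets other than controls had a log2 value of at least 4 on an array. With 3 arrays per group, the median standard error (SE) of a log2 difference was 0.66. Levels are mean log2 GCRMA values ± SD (n = 3), and adjusted p-values are those of limma with Benjamini-Hochberg adjustment. Log2 differences are LNvs minus elav neurons, ZT15 minus ZT3, mutant minus wild type, or cyc0 minus per0. Where the 3 arrays of a group all lay below log2 4, the fold is given as "at least", from the mean of the brighter group minus that working level, which is not a measured detection limit. Each gene named as higher or lower passed an adjusted p of 0.05 with no overlap between the arrays of the groups compared, except cwo between LNvs and elav neurons, whose arrays overlapped.

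The comparison of wild-type LNvs with elav neurons at ZT15 asked which transcripts mark the pacemaker neurons. At that time the wild-type LNvs carried more Pdf, clock-gene and Irk1 transcript, while ct, oc and Hrb87F transcripts were higher in the elav neurons. Pdf stood at 12.50 ± 0.10 in LNvs and 3.70 ± 0.73 in elav neurons, a log2 difference of 8.80 (SE 0.48, adjusted p = 3.9e-09). Since the Pdf promoter also drove the reporter used for the sort, this difference is no independent finding. The clock gene tim stood at 10.89 ± 0.18 against 4.37 ± 1.22 (adjusted p = 2.43e-06). Irk1, an inwardly rectifying potassium channel, reached 7.89 ± 1.48 in LNvs and was at least 14.8-fold higher than in elav neurons (adjusted p = 0.000101). Tbh, which encodes tyramine beta-hydroxylase, was at least 44.8-fold higher (adjusted p = 7.61e-05) and the insulin-like peptide gene Ilp7 at least 15.5-fold higher (adjusted p = 0.000882). These differences were not common to all LNv groups. In wild-type LNvs at ZT3 and in cyc0 LNvs, tim averaged 2.97 and 2.98, against 4.37 in elav neurons. Irk1 averaged 3.76 and 3.04 there, against 2.63 in elav neurons. In per0 LNvs tim and Irk1 averaged 10.89 and 6.40. In per0 and cyc0 LNvs, Ilp7 averaged 3.13 and 4.05, against 2.61 in elav neurons. Tbh averaged 6.25 in wild-type LNvs at ZT3 and 5.98 and 4.24 in per0 and cyc0, against 2.95 in elav neurons. The small heat-shock protein gene l(2)efl (log2 difference 6.42), the microtubule-associated protein gene futsch (5.09) and the adenylyl cyclase gene Ac13E (5.06) were also among the 12 genes with the largest positive difference.

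Among the genes with the largest negative differences, the homeobox gene ct lay at 2.57 ± 0.04 in LNvs and 9.24 ± 1.26 in elav neurons, at least 37.7-fold lower in LNvs (adjusted p = 9.26e-06), although another probe set of ct differed by -0.95 (adjusted p = 0.364). The homeobox genes oc, tup and pdm3 were at least 15.8-fold, 15.1-fold and 14.2-fold lower in LNvs. The nuclear factor gene dac differed by -5.62 (adjusted p = 0.00218) and the LIM homeobox gene Lim1 by -5.09 (adjusted p = 0.000174). Hrb87F, which encodes an RNA-binding protein of the hnRNP family, lay at 5.48 ± 1.11 in wild-type LNvs and 11.78 ± 0.20 in elav neurons (adjusted p = 9.26e-06). This difference was not common to all LNv groups. Hrb87F also averaged 5.48 in wild-type LNvs at ZT3, but 11.20 and 11.04 in per0 and cyc0 LNvs. The transcript of elav itself, whose driver labelled the comparison cells, lay at 5.58 ± 0.72 in LNvs and 8.75 ± 0.46 in elav neurons (adjusted p = 0.00191).

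Gene lists fixed before the data were examined were tested with camera. All 5 tested CLK/CYC targets of the clock loop (per, tim, vri, Pdp1 and cwo) were higher in LNvs (5 adjusted over the list alone; list adjusted p = 1.22e-06, and adjusted p = 0.00553 with an estimated correlation). Of 7 activity-regulated and JNK-response genes, CG14186, cbt, sr and Jra were higher (5 adjusted over the list alone; list adjusted p = 0.000332, and adjusted p = 0.0342 with an estimated correlation), with CG14186 at 11.37 ± 0.32 against 8.38 ± 0.42. Higher transcripts were also called for 12 of 46 oxidative phosphorylation subunits, such as ND-ASHI (5.60) and COX7C (4.62), with 19 adjusted over the list alone (list adjusted p = 7.6e-06, and adjusted p = 0.34 with an estimated correlation). The same held for 6 of 33 ribosomal protein genes, such as RpS7 (4.07), with 12 adjusted over the list alone (list adjusted p = 5.3e-06, and adjusted p = 0.427 with an estimated correlation). Of 15 pan-neuronal and synaptic vesicle genes 4 were higher, among them the calcium channel gene cac (4.27) and futsch, and elav was lower (6 and 1 adjusted over the list alone; list adjusted p = 0.0251, and adjusted p = 0.43 with an estimated correlation). Of 9 sodium, calcium and cation channel genes, unc79 (3.50), unc80 and cac were higher (3 adjusted over the list alone; list adjusted p = 0.0489, and adjusted p = 0.43 with an estimated correlation). That list had adjusted p = 0.0508 without cyc0 replicate 3 and 0.0902 without wild-type ZT15 replicate 1, arrays left out after the data were seen because they stood apart from their groups. Pdf alone passed among 5 LNv-associated genes (2 adjusted over the list alone; list adjusted p = 0.00386, and adjusted p = 0.112 with an estimated correlation). Without Pdf, left out after the data were seen, the other 4 genes of that list, below the size otherwise tested, had a median of 1.18 and the list did not pass (adjusted p = 0.149). The sodium, calcium and cation channels then did not pass either (adjusted p = 0.055).

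All 4 tested neuroblast markers (wor, mira, insc and ase) were lower, with mira at 2.73 ± 0.44 against 6.92 ± 1.94, and the list was below the size tested with camera. CycE, Mcm5, Incenp and tum were lower among 9 cell cycle genes, with CycE at least 23.5-fold lower (5 adjusted over the list alone; list adjusted p = 4.55e-05, and adjusted p = 0.112 with an estimated correlation). Among 8 immature neuron genes pros (-5.16), chinmo, Syp and Delta were lower (5 adjusted over the list alone; list adjusted p = 5.3e-06, and adjusted p = 0.112 with an estimated correlation), although other probe sets of chinmo and Syp differed by -0.60 and -1.11 (adjusted p = 0.698 and 0.35). The transmitter genes ChAT (-3.17), VAChT and Gad1 were lower and Tbh was higher among 6 tested markers of fast transmitters and monoamines (list adjusted p = 0.149). Pal2 (4.33), 7B2 and Phm were higher among 8 genes of peptide processing and dense-core vesicles, a list that did not pass (adjusted p = 0.0532). Of 7 glia markers Gs2 was higher and nrv2 lower (list adjusted p = 0.77). Irk1 and SK were higher among 8 potassium channel genes (list adjusted p = 0.136), nAChRbeta1 among 11 neurotransmitter receptor genes (0.149), cyc among 8 other clock factors (0.149) and stv among 6 heat-shock genes (0.611). Other probe sets of SK and cwo did not pass, at 2.03 and 2.84 (adjusted p = 0.0864 and 0.0876). No member passed among 7 neuropeptide genes other than Pdf (list adjusted p = 0.641), 3 hemocyte markers, 2 fat body markers, 1 photoreceptor marker and 1 muscle marker, lists also below that size, and none of 7 antimicrobial and immune genes on the array reached the level needed for a test.

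**Figure D1:**
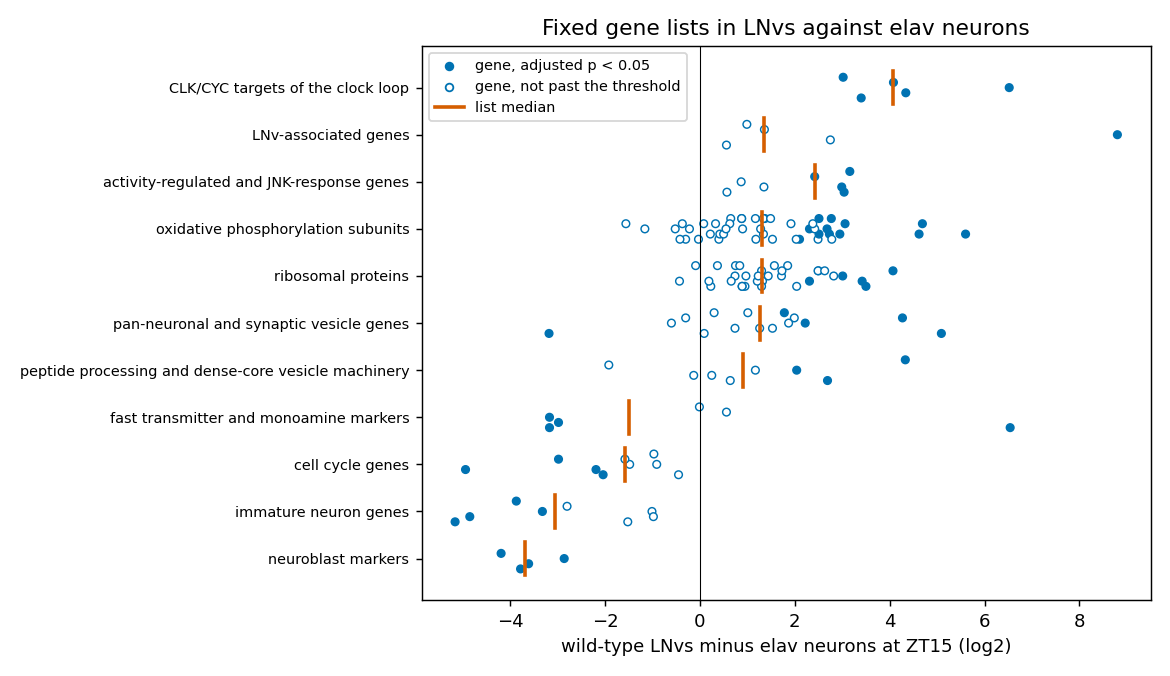
Each point is a gene of a list fixed beforehand, placed by the log2 difference between wild-type LNvs and elav neurons at ZT15 (3 arrays each) and filled where its adjusted p passed the threshold; the orange bar marks the list median. The clock targets lie to the right of 0 with a median of 4.08, and the neuroblast markers to the left with a median of -3.70.

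In this comparison 729 of 5829 probe sets passed, 423 higher and 306 lower in LNvs, for 584 of 4721 named genes, and 1584 had an unadjusted p under 0.05. The median over all probe sets was 0.11, against -0.07 after centring and 0.01 after quantile normalization. With no filter on low values 454 passed. Of the calls, 51% were higher in LNvs after centring and 48.3% after quantile normalization, in place of 58%. The calls of cwo, sr, Jra, ase, Incenp, tum, Phm, Gs2, nrv2, nAChRbeta1, cyc and stv were each lost with at least 1 array left out (largest adjusted p over the alternatives 0.167). The call of Gs2 was also lost after centring and those of Gs2 and nAChRbeta1 after quantile normalization. Calls lost only with no filter or in a fit to the 6 arrays compared were those of RpS7 and insc (largest adjusted p = 0.0628).

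The comparison of ZT15 with ZT3 in wild-type LNvs asked which transcripts differ between early night and morning. The clock genes tim and per, Irk1, Cipc, Pura and sNPF were higher at ZT15, and CG31675, CG9338, Dh31 and Ntl were higher at ZT3. The transcript of tim lay at 10.89 ± 0.18 at ZT15 and was at least 119-fold higher than at ZT3 (adjusted p = 2.21e-07), and per, at 7.24 ± 1.32, was at least 9.45-fold higher (adjusted p = 0.0194). Pdp1 differed by 3.18 (SE 0.69, adjusted p = 0.0333). Irk1 rose from 3.76 ± 0.63 at ZT3 to 7.89 ± 1.48 at ZT15 (adjusted p = 0.00304). The study is known for its work on Irk1 and on the potassium channel gene Shaw, which was not checked here. Both genes stood in the set fixed beforehand, so that Irk1 is no independent pick. Shaw stayed below the level needed for a test.

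Other transcripts higher at ZT15 were Cipc, the fly counterpart of a mammalian CLOCK-interacting protein, at 10.18 ± 0.34 against 5.70 ± 1.80 (adjusted p = 0.00805), and Pura at 9.94 ± 0.15 against 5.73 ± 0.56 (adjusted p = 5e-04). The short neuropeptide F precursor gene sNPF was at least 8.17-fold higher (adjusted p = 0.0231) and the adhesion gene CadN at least 8.27-fold higher (adjusted p = 0.0268), and the synaptic cleft protein gene hig differed by 3.82 (adjusted p = 0.0194). Higher at ZT3 were CG31675, at 9.60 ± 0.42 against 3.50 ± 0.67 (adjusted p = 0.000135), and CG9338, which encodes a protein with a Ly6 domain, at 8.74 ± 0.70 against 3.63 ± 0.48 (adjusted p = 0.000405). The diuretic hormone gene Dh31 was at least 7.21-fold and the transporter gene Ntl at least 7.13-fold higher at ZT3 (adjusted p = 0.00291 and 0.000376). DIP-gamma, a cell-surface protein gene of the immunoglobulin superfamily (log2 difference -3.83), and the folate enzyme gene Nmdmc (-4.83) were higher at ZT3 too. Tl, the Toll receptor gene, was lower at ZT15 by the probe set used (-3.93, adjusted p = 0.0206), while another of its probe sets differed by 2.15 (adjusted p = 0.371). Pdf itself stood at 12.67 ± 0.10 at ZT3 and 12.50 ± 0.10 at ZT15 (adjusted p = 0.997).

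Of the 5 clock targets tim, per and Pdp1 passed (4 adjusted over the list alone), vri differed by 1.32 (SE 0.55, adjusted p = 0.444) and cwo by -0.36 (SE 0.94, adjusted p = 0.991). The list was higher at ZT15 (list adjusted p = 1.13e-08, and adjusted p = 0.00189 with an estimated correlation). None of 46 oxidative phosphorylation genes passed singly, with a list median of 0.73 (list adjusted p = 1.47e-07, and adjusted p = 0.497 with an estimated correlation). None of 7 activity-regulated and JNK-response genes passed either, with a median of 0.46 (1 adjusted over the list alone; list adjusted p = 0.048, adjusted p = 0.251 with an estimated correlation, and adjusted p = 0.0566 without cyc0 replicate 3, which enters through the shared spread). No other list passed, although sNPF and Dh31 did in opposite directions among the neuropeptides and Ddc, the dopa decarboxylase gene, did among the transmitter markers (log2 difference -2.77, adjusted p = 0.0348). The glial marker repo lay at 5.61 ± 1.91 at ZT3 and 2.98 ± 0.18 at ZT15 (adjusted p = 0.191).

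**Figure D2:**
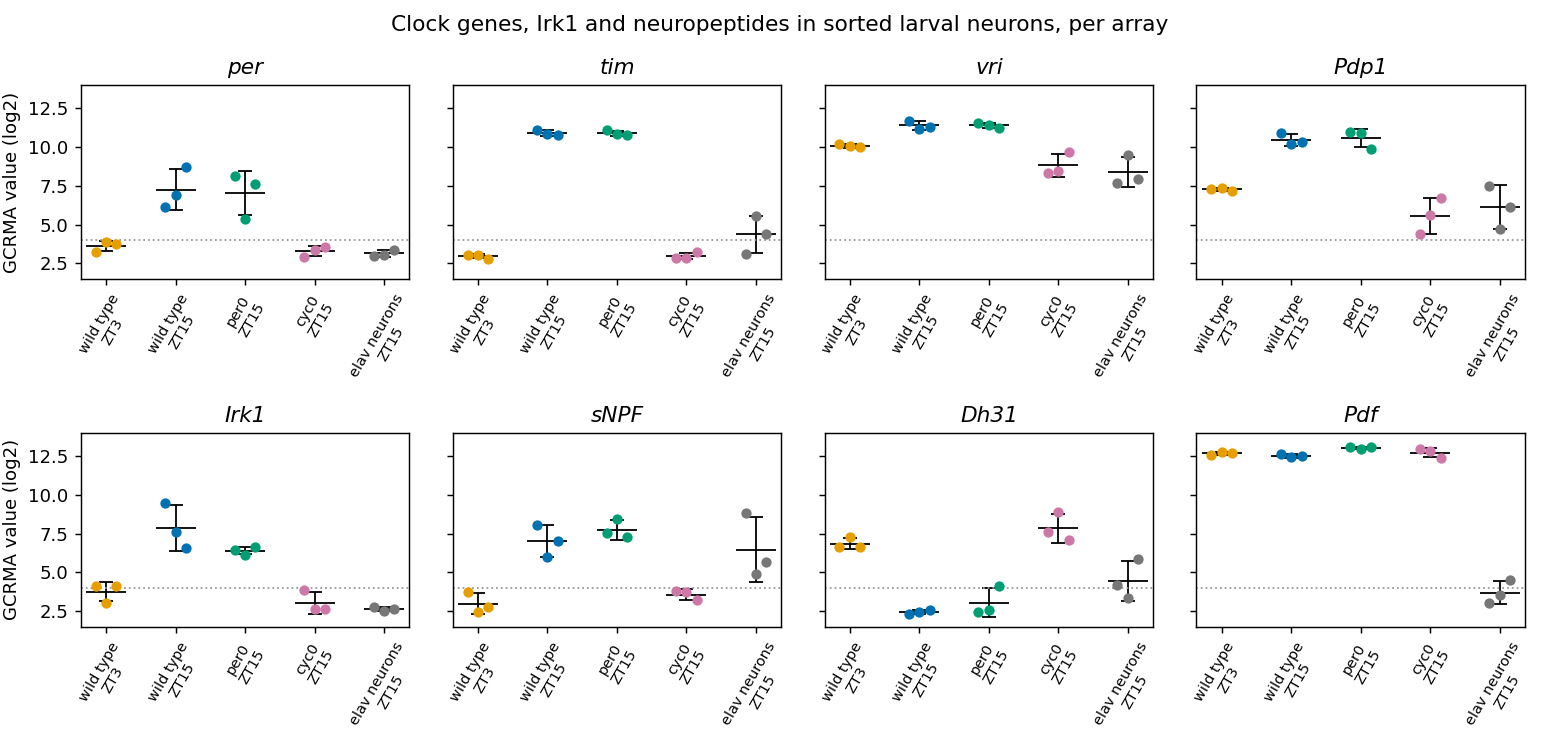
Log2 GCRMA values of 8 genes in the 5 groups; points are arrays, horizontal bars the means and whiskers the SD (n = 3), and the dotted line marks log2 4. For tim, wild type at ZT15 and per0 both average 10.89, while wild type at ZT3 and cyc0 average 2.97 and 2.98; Dh31 averages 6.85 at ZT3 and 7.85 in cyc0 against 2.44 at ZT15 and 3.04 in per0.

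Between the times 46 probe sets passed, 25 higher at ZT15 and 21 higher at ZT3, for 37 named genes, and 515 had an unadjusted p under 0.05. A fit to the 6 wild-type LNv arrays alone called 6, and the count was 27, 20 and 29 without ZT3 replicates 1, 2 and 3 and 30 and 27 without ZT15 replicates 2 and 3. The calls of per, Pdp1, sNPF, CadN, hig, Tl and Ddc were each lost with at least 1 array left out (largest adjusted p over the alternatives 0.309). The call of Pdp1 was also lost after centring and after quantile normalization, and that of Ddc with a prior with trend and robust estimation. Calls lost only with no filter or in the fit to 6 arrays were those of Irk1, Cipc, Ntl, DIP-gamma and Nmdmc (largest adjusted p = 0.196).

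The per0 mutant, which lacks the function of period, a repressor of CLK/CYC, was compared with wild type at ZT15. The per transcript itself lay at 7.04 ± 1.45 in per0 and 7.24 ± 1.32 in wild type (adjusted p = 0.913). The labels name no lesion, and a mutation that leaves the transcript in place is not checked by its level. Mean levels of tim, vri and Pdp1 were 10.89, 11.39 and 10.58 in per0 against 10.89, 11.40 and 10.47 in wild type, and none of the 5 clock targets passed (list adjusted p = 0.56). The largest positive difference among the genes named was that of Hrb87F, at 11.20 ± 0.16 in per0 and 5.48 ± 1.11 in wild type (adjusted p = 9.84e-05). The neuropeptide gene Capa was at least 12.8-fold higher (adjusted p = 0.00403), with 9.14, 8.74 and 5.14 on the per0 arrays. The gene ppk20, of the pickpocket family of sodium channels, was at least 7.13-fold higher (adjusted p = 6.81e-05). The dipeptidyl peptidase gene ome was at least 4.84-fold higher (adjusted p = 0.0066). Lower in per0 were Ilp7, at 3.13 ± 1.03 against 7.96 ± 0.98 (adjusted p = 0.0107), the transcription factor gene NFAT (log2 difference -4.58, adjusted p = 0.0066), the adhesion gene Con, at least 4.74-fold (adjusted p = 0.00628), Tbh (log2 difference -3.51, adjusted p = 0.033), and the glial marker Gs2, at 3.91 ± 0.47 against 6.90 ± 1.28 (adjusted p = 0.0225).

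By list, Capa passed among 7 neuropeptide genes (2 adjusted over the list alone; list adjusted p = 0.185), Syp among 8 immature neuron genes (log2 difference 2.77, against 0.06 for another probe set; list adjusted p = 0.878) and Gs2 among 7 glia markers. Tbh was lower among 6 transmitter markers (2 adjusted over the list alone; list adjusted p = 0.0131, and adjusted p = 0.257 with an estimated correlation). The median of that list was -0.30 and its mean -1.50, so that the mean rested largely on a few members, though none of the 6 was positive. Vmat differed by -4.53 by the probe set used and by -1.21 by another (adjusted p = 0.0742 and 0.432). The medians of 33 ribosomal protein and 46 oxidative phosphorylation genes were -0.46 and -0.30, with no member past the threshold (list adjusted p = 0.00102 and 0.00563, and adjusted p = 0.546 and 0.529 with an estimated correlation). The median of all probe sets was 0.24 in this comparison, 0.06 after centring the arrays and 0.04 after quantile normalization, where the ribosomal medians were -0.64 and -0.34 in that order and the oxidative phosphorylation medians -0.48 and -0.46. All 9 cell cycle genes had a positive difference (8 after quantile normalization), with a median of 1.02 and none past the threshold (list adjusted p = 0.0686). Without wild-type replicate 1, left out after the data were seen, the lists of other clock factors, receptors, activity-regulated genes and glia markers were lower in per0, each with adjusted p = 0.0491, against 0.125, 0.0686, 0.0792 and 0.0686 with all arrays. With an estimated correlation and all arrays, each of these lists had adjusted p = 0.473.

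Between per0 and wild type 69 probe sets passed, 27 higher and 42 lower in per0, for 60 named genes, and 959 had an unadjusted p under 0.05. The larger direction depended on the setting. Of the calls, 68.6% were higher with array weights, whose estimation stopped before it converged, and 66.7% in a fit to the 6 arrays compared, in place of 39.1%. The count was 6 in a fit to the 6 arrays compared, 40 with no filter, 111 and 120 after centring and quantile normalization, 142, 26 and 27 without wild-type replicates 1, 2 and 3, and 45, 30 and 25 without per0 replicates 1, 2 and 3. The calls of Ilp7, Tbh, Gs2 and Syp were each lost with at least 1 array left out (largest adjusted p over the alternatives 0.166), and those of Capa, NFAT and Con only with no filter or in the fit to 6 arrays (0.112).

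The cyc0 mutant lacks the function of cycle, the partner of CLK in transcriptional activation. The cyc transcript lay at 4.71 ± 0.80 in cyc0 and 6.35 ± 1.42 in wild type at ZT15 (adjusted p = 0.207), a check with the same limit as for per. Transcripts of 4 of the 5 clock targets were lower in cyc0, namely tim at least 119-fold (adjusted p = 2.25e-07), per at least 9.45-fold (adjusted p = 0.00431), Pdp1 by a log2 difference of -4.92 (adjusted p = 0.000888) and vri by -2.57 (adjusted p = 0.0139), while cwo differed by -1.77 (SE 0.94, adjusted p = 0.316). The list was lower in cyc0 (4 adjusted over the list alone; list adjusted p = 2.98e-10, and adjusted p = 0.000977 with an estimated correlation). Irk1 was at least 14.8-fold lower (adjusted p = 0.000533) and sNPF at least 8.17-fold lower (adjusted p = 0.0251). Pura differed by -4.72 and Cipc by -4.48 (adjusted p = 0.000104 and 0.00368). Tbh lay at 4.24 ± 0.18 against 9.49 ± 1.33 (adjusted p = 0.00107).

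Higher in cyc0 were Hrb87F (log2 difference 5.56, adjusted p = 8.54e-05), Dh31, at least 14.4-fold (adjusted p = 0.000257), and TkR86C, a receptor gene of the tachykinin type, at least 19.9-fold (adjusted p = 8.54e-05). The prohormone convertase gene amon (3.99, adjusted p = 0.0192) and the receptor phosphatase gene Ptp99A (4.33, adjusted p = 0.00426) were higher too. RpS21 was lower among 33 ribosomal protein genes, with 10 lower adjusted over the list alone, and none passed among 46 oxidative phosphorylation genes (medians of -1.32 and -0.77; list adjusted p = 2.98e-10 and 1.83e-06, and adjusted p = 0.398 for both with an estimated correlation). The median of all probe sets was 0.17, against -0.02 after centring and 0.05 after quantile normalization, where the ribosomal medians were -1.51 and -0.79 in that order. No other list passed with all arrays. Without wild-type replicate 1 the 7 activity-regulated and JNK-response genes were lower as a list (adjusted p = 0.0351, against 0.0782 with all arrays, and adjusted p = 0.395 with all arrays and an estimated correlation).

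Levels of transcripts of elav neurons were also compared between the mutant and wild-type LNvs. Over 241 probe sets higher in elav neurons than in wild-type LNvs at ZT3, the array medians were 4.95, 5.10 and 5.44 in cyc0, 4.44, 4.69 and 5.43 in per0, and 4.38, 3.82 and 4.18 in wild type at ZT15. In wild type at ZT3, where the set was chosen to be low, they were 3.47, 3.95 and 4.63, so that wild-type and per0 arrays overlapped. Replicate 3 of cyc0 correlated with elav replicate 3 at r = 0.779 across probe sets, which are not independent replicates, and with the other cyc0 arrays at a mean of 0.785. Closeness to another group was not confined to this array. With per0 replicate 1, wild-type ZT15 replicate 1 correlated at 0.828 and cyc0 replicate 2 at 0.894, against means of 0.786 and 0.811 within their own groups. Among the 4 neuroblast markers and the cell cycle, immature neuron and glia lists, the medians in cyc0 were 0.44, 0.58, 0.55 and -0.14. These medians were 0.24, 0.38, 0.35 and -0.33 after centring and 0.29, 0.31, 0.50 and -0.17 after quantile normalization.

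Between cyc0 and wild type 169 probe sets passed, 89 higher and 80 lower in cyc0, for 140 named genes, and 1128 had an unadjusted p under 0.05. Centring the arrays gave 265 with 41.1% higher in place of 52.7%, quantile normalization gave 256, a fit to the 6 arrays compared called 35, and the count was 62, 258 and 110 without cyc0 replicates 1, 2 and 3 and 95 without wild-type replicate 2. The calls of vri, sNPF, amon and RpS21 were each lost with at least 1 array left out (largest adjusted p over the alternatives 0.157), that of vri also after quantile normalization. Calls lost only in the fit to 6 arrays were those of per, Irk1 and Ptp99A (largest adjusted p = 0.0687).

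Both mutants were set against the same 3 wild-type arrays, and 38 probe sets passed in both, 12 higher and 26 lower, all in the same direction. Independent lists of these sizes would share 0.412 and 0.576. In 50 simulations of unchanged groups against shared controls 0 were shared, a number set by their few calls, at most 1 per group. Across probe sets, the differences of the mutants correlated at r = 0.653 against a simulated 0.499, with a covariance of 0.805 against 0.246. The wild-type arrays were too few to split, so that part of the excess may come from the shared controls. Hrb87F and the cytochrome P450 gene Cyp4p2 were higher in both mutants and Tbh was lower.

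**Figure D3:**
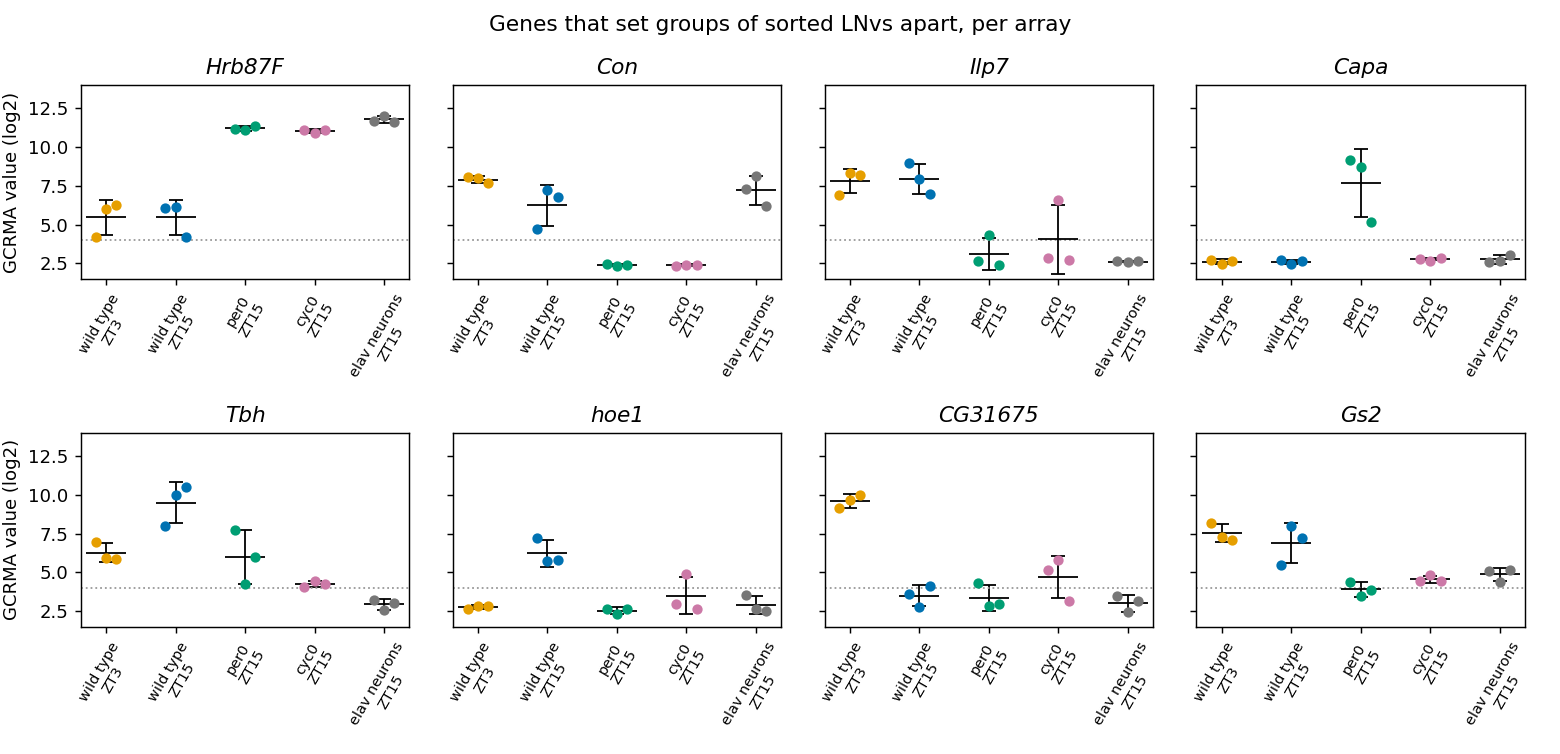
Log2 GCRMA values of 8 genes in the 5 groups; points are arrays, horizontal bars the means and whiskers the SD (n = 3), and the dotted line marks log2 4. Hrb87F averages 5.48 at ZT3 and 5.48 at ZT15 in wild type and 11.20 and 11.04 in per0 and cyc0, and CG31675 averages 9.60 at ZT3 and at most 4.69 in the other groups.

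The comparison of cyc0 with per0, which share the Pdf-RFP reporter, asked which transcripts differ between loss of the activator and loss of the repressor. Any other difference between these mutant lines cannot be told apart from the loss of either gene. Clock targets were lower in cyc0, with tim at least 119-fold (adjusted p = 2.25e-07), Pdp1 by a log2 difference of -5.02 (adjusted p = 0.000761), per at least 8.22-fold (adjusted p = 0.0134) and vri by -2.57 (adjusted p = 0.0307), while cwo differed by -1.47 (adjusted p = 0.651). That list was lower in cyc0 (4 of 5 adjusted over the list alone; list adjusted p = 5.04e-13, and adjusted p = 0.000329 with an estimated correlation). Irk1 was at least 5.27-fold lower in cyc0 (adjusted p = 0.0163), Capa at least 12.8-fold (adjusted p = 0.00188), sNPF at least 13.4-fold (adjusted p = 0.0176), and Pura differed by -4.11 (adjusted p = 0.000723). Higher in cyc0 were TkR86C, at least 19.9-fold (adjusted p = 7.22e-05), Dh31 (log2 difference 4.80, adjusted p = 0.000856), DIP-gamma (3.44, adjusted p = 0.00352) and the cyclic-nucleotide-gated channel gene CngA (4.44, adjusted p = 0.0157). The RNA-binding protein gene Imp was higher by the probe set used (3.28, adjusted p = 0.00813), while its other probe sets did not pass.

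Heat-shock genes had a median of -1.02 over 6 members, ribosomal protein genes of -0.67 and oxidative phosphorylation genes of -0.42, with no member past the threshold (list adjusted p = 0.00417, 0.000469 and 0.0355, and adjusted p = 0.585, 0.667 and 0.675 with an estimated correlation). After quantile normalization the heat-shock and oxidative phosphorylation medians were -0.65 and -0.20, with 17 of 46 oxidative phosphorylation genes positive in place of 12. Without cyc0 replicate 3, left out after the data were seen, the ribosomal and oxidative phosphorylation lists had adjusted p = 0.197 and 0.0535. No other list passed; among 7 neuropeptide genes Dh31 was higher and sNPF and Capa were lower (1 and 3 adjusted over the list alone; list adjusted p = 0.26).

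Between the mutants 46 probe sets passed, 20 higher and 26 lower in cyc0, for 35 named genes, and 586 had an unadjusted p under 0.05. Quantile normalization gave 75 with 58.7% higher in place of 43.5%, a fit to the 6 mutant arrays called 21, no filter gave 24, and the count was 27, 29 and 26 without per0 replicates 1, 2 and 3 and 20 without cyc0 replicate 1. The calls of per, vri, Irk1, sNPF, CngA and Imp were each lost with at least 1 array left out (largest adjusted p over the alternatives 0.211), that of vri also after centring and after quantile normalization. The fit to 6 arrays alone ended that of Capa (largest adjusted p = 0.118).

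The difference by time and the difference between the mutants rest on separate arrays. Of the 46 probe sets called by time and the 46 called between cyc0 and per0, 11 were shared, all with the same sign when ZT15 minus ZT3 is set against per0 minus cyc0. They comprised 9 higher and 2 lower, where independent lists would share 0.112 and 0.0721, numbers that leave out the shared spread. The higher probe sets belonged to tim, with both of its probe sets, per, Pdp1, Irk1, sNPF, Pura, CG13054 and an unnamed probe set, listed for being shared after the values were seen, and the lower probe sets to Dh31 and DIP-gamma. For sNPF the levels were 7.03 at ZT15 and 7.74 in per0 against 2.98 at ZT3 and 3.58 in cyc0, and for DIP-gamma 3.41 and 3.70 against 7.23 and 7.14. Across all probe sets, which are not independent replicates, the Pearson correlation was r = 0.150 and the Spearman correlation 0.0926. With no filter on low values 5 probe sets were shared, and the number was 7 and 6 without ZT3 replicate 3 and ZT15 replicate 3, 5 and 6 without per0 replicates 1 and 3, and 7 without cyc0 replicate 1 or 3. Among settings added for this count after the data were seen, fits to the 6 arrays of each comparison shared 3 (tim, Pura and Dh31), and array weights gave 19.

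**Figure D4:**
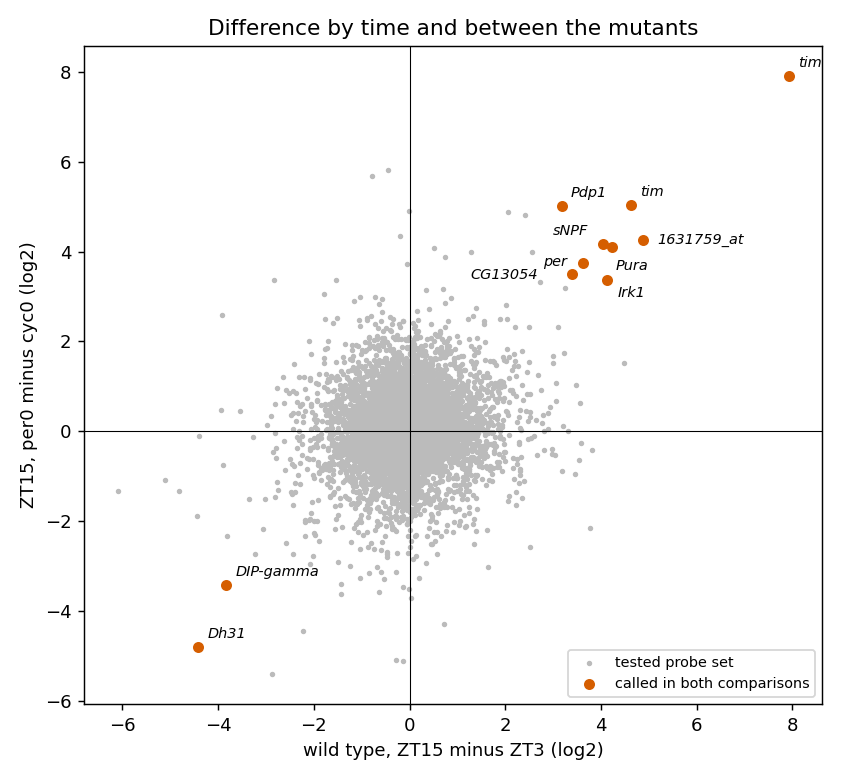
Each point is a tested probe set, with the wild-type difference between ZT15 and ZT3 on the horizontal axis and the difference between per0 and cyc0 at ZT15 on the vertical axis, both in log2 units. The 11 probe sets called in both comparisons are coloured and named, with a tim probe set farthest out at 7.92 and 7.91.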

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

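Leaving cyc0 replicate 3 or wild-type ZT15 replicate 1 out of the list tests, Pdf out of the LNv-associated list, the check of list medians under other scalings, and, for the calls shared by time and mutants, array weights, the fit to 6 arrays, 1 probe set per gene and a minimum fold, were chosen after seeing the data; the other alternatives were fixed beforehand. With no filter on low values, which tests more probe sets, the counts were 454 for LNvs against elav neurons, 40 for per0, 24 for cyc0 against per0 and 5 shared between time and mutants. Centring gave 111 for per0 and 265 for cyc0, and quantile normalization gave 120, 256 and, for cyc0 against per0, 75; the cause was not tested. Array weights gave 456, 943 and 817, and 19 shared by time and mutants, with weights of 3.26 for per0 replicate 1 and 4.27 for cyc0 replicate 1, but their estimation stopped before it converged. A fit to the 6 arrays compared, with fewer degrees of freedom, gave 6 by time, 6 for per0, 35 for cyc0, 21 between the mutants and 3 shared by time and mutants. Of 22 list calls 5 held with an estimated correlation, 18 lists passed without cyc0 replicate 3 and 26 without wild-type ZT15 replicate 1, and 20 passed with Pdf left out of the LNv-associated list. With each array left out in turn, the counts ran from 491 to 641 for LNvs against elav neurons, 20 to 44 by time, 25 to 142 for per0, 62 to 258 for cyc0, 20 to 67 between the mutants and 5 to 10 for those shared by time and mutants. All other alternatives gave counts within 1.5 times the value reported.

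With the replicate number as a block the counts were 713, 39, 46, 156 and 40 in the order of the comparisons, 9 shared by time and mutants and 21 lists, with the sodium and calcium channel list in LNvs at adjusted p = 0.0544; among genes named, it also ended the calls of Pdp1 and Ddc by time, Tbh in per0 and vri between the mutants. Little pairing by number was seen: 5 of 30 pairs with the same number deviated together at r over 0.1, and 4 of 15 arrays correlated best with their own number. The labels do not say whether arrays with the same number were processed together. Of 174 calls of single genes, 1357 of 1542 values under other settings and 780 of 1044 with an array left out stayed past the threshold, and none of these changed direction. Under other scalings the sign of the median turned only in lists that had not passed, such as the neuropeptides in LNvs against elav neurons. Values near the lower end of the GCRMA scale limit the folds that can be given for genes such as tim at ZT3.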

Other observations

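The tests given here were chosen after the results were seen, except the numbers of shared calls after centring and quantile normalization, which were planned. The transcripts called by time of day in wild-type LNvs were followed into both mutants at ZT15. Of the 25 probe sets higher at ZT15, the cyc0 mean lay nearer to the wild-type ZT15 mean for 4 and the per0 mean for 13. Of the 21 higher at ZT3, the cyc0 mean lay nearer to ZT15 for 14 and the per0 mean for 17. Some transcripts of the morning group were low in both mutants: CG9338 averaged 8.74 at ZT3, 3.63 at ZT15, 3.22 in per0 and 4.29 in cyc0, and the transporter gene Ntl 6.83, 2.44, 2.47 and 2.59. Others were high in cyc0, such as Ktl, at 9.63, 5.81, 6.10 and 8.44, and Dh31. Nearness of means was not tested, and these genes were singled out after their values were seen.

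In each comparison the real split gave the most calls, and 1 of the 10 splits of 6 arrays into 3 and 3, the real split itself, gave a result as large. The calls and the highest number in another split were 729 and 0 for LNvs against elav neurons, 46 and 13 by time, 69 and 0 for per0, 169 and 5 for cyc0, and 46 and 14 between the mutants. These splits are too few for a share under 0.05.

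The 11 probe sets shared by time and mutants, among them tim, per, Pdp1, Irk1, sNPF and Dh31, had the same sign in both comparisons. These share no array but share the estimate of the spread. Fits to the 6 arrays of each comparison, with separate spreads, called 6 and 21 and shared 3. Among 100 combined splits of the wild-type and the mutant arrays, 1 gave as many shared calls, the real split itself, with a highest other number of 0. Other splits of either set mixed the groups and made few calls, at most 13 and 14 taken singly, which left few to be shared. The splits therefore cannot exclude chance by themselves. Independent lists would share 0.112 and 0.0721 in place of 9 and 2, numbers that leave out the shared spread. At least 10 shared calls were found after centring or quantile normalization of the deposited values. The median over all probe sets was only -0.06 for ZT15 minus ZT3 and -0.04 for cyc0 minus per0. Rescaling could therefore hardly remove most of these calls, and their number is no separate evidence about a difference in scale between arrays. Other steps of the authors' GCRMA processing, such as the background, could not be tested on these values and stay open. Over all 11 probe sets the elav level minus the higher LNv level had a median of -4.16 (SD 1.40). This argues only against transcript added by neurons like the average elav neuron as the cause of the higher levels of the whole set. The probe sets were chosen through those higher levels, which lowers this median. Dilution of LNv transcripts by other neurons in the groups with lower levels would also go with a low elav level, so that it stays open. The elav level is a mean over many neurons, so that a rare kind with high levels stays open. For sNPF the elav level minus the higher LNv level was -0.92 with overlapping arrays, and other neurons stay open for it in any case. The differences of time and genotype that the design names stay open as well, untested.

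Of the 38 probe sets called in both mutants against wild type at ZT15, 13 were also called in the same direction in both mutants against wild type at ZT3, such as Hrb87F and Cyp4p2, 7 were called between ZT15 and ZT3 in wild type, and the remaining 18, which were not weighed, include Tbh (mean 6.25 at ZT3, 9.49 at ZT15, 5.98 in per0 and 4.24 in cyc0). Lists of the same lengths from simulated unchanged groups, with the same mutant arrays in both comparisons, shared at most 6 with probe sets drawn independently and at most 14 with residuals of whole arrays, so that chance values of the wild-type ZT15 arrays stay open for the set. For the 13 a difference of line or reporter cannot be told apart from loss of the clock either, since both mutants carried another line and reporter than wild type. For the 7 between the times, which include both tested probe sets of CG34353, simulations with the differences of the mutants and none by time gave at most 3 and 2 such calls. These simulations differed from the data, with a mean of 134 and 93.7 probe sets shared by the mutants in place of 38. The 7 were picked for their call by time. Their number argues only against a line or reporter difference without any difference by time. Chance values of the ZT15 arrays stay open for these 7, as does the difference of genotype, which was not tested.

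Over 241 probe sets higher in elav neurons than in wild-type LNvs at ZT3, the median difference from wild type at ZT15 was 0.59 in per0 and 0.72 in cyc0, against 0.24 and 0.17 over all probe sets, with 191 and 190 of them higher, of which 6 and 18 passed. A candidate explanation is that more of the sorted cells in the mutant lines were other neurons. The 7 fixed markers lower in LNvs (ase, ChAT, Gad1, insc, mira, VAChT and wor) had a median difference of 0.42 in cyc0 (SD 0.41), below the median of the set by less than their SD, which leaves that explanation open, although the gate kept only the brightest cells. These markers were picked as low on the same wild-type ZT15 arrays that enter the difference, which can raise it. In per0 the marker median was 0.23 (SD 0.44). A change in LNvs of the mutants themselves was not tested.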
